A study of Mus musculus with 9 samples.

How the data were processed

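Total RNA of 4T1 cells was extracted with TRIzol and polyadenylated RNA was sequenced as paired reads on a HiSeq2500, per the labels' protocols, which also state that stable clones were selected with Zeocin. Per the submitters' processing notes, reads were aligned to mm10 with TopHat2 2.0.13 and Bowtie2 2.2.3, and expression was estimated with Cufflinks 2.2.1. The authors' deposited gene table holds FPKM values of 24067 genes in 9 libraries, and FPKM values of the other deposited tables differed from it by at most 4e-16. The deposited comparison table, which the authors limited to genes above 0 in all 9 libraries, also holds log2 values of FPKM after quantile normalization. These were recomputed to within 5e-09. For each pair of codes the authors give a signed fold, a raw p-value and an adjusted p-value per the file headers. For C-20 over NTC, an unequal-variance test recomputed here differed from the authors' raw p-value by at most 2e-15. Raw p-values of the other comparisons were not recomputed. The authors' group means equalled those of NTC, C-20 and C-26 to 3e-14.

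Libraries were grouped by title (control, clone 2, clone 3, with 3 libraries each) and, crossed with it, by the code of the description (NTC is replicate 1, C-20 replicate 2 and C-26 replicate 3 of each title). The leading number of the description is 1 for control, 2 for clone 2 and 4 for clone 3. Codes were also compared with the title group as block, because libraries of 1 title resembled each other: 9 correlations of deviations ran from 0.260 to 0.883, and 9 of 9 libraries matched best with their own title.

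Counts of reads are not analysed here, so absolute depth is unknown. Relative depth, taken from the steps of FPKM of 9684 low genes with a single transcript, ran from 0.889 to 1.142. Genes above 0 numbered 14883 to 18283 per library, and FPKM sums ran from 439018.1 to 560091.9, with 7.93% to 9.93% in the 10 most abundant genes. On simulated data 2-fold changes were recovered for 38.8% of genes in clone 3 against control, 22.4% in C-26 against NTC and 50.7% with the block, and 4-fold changes for 93.9%, 77.3% and 95.5%, with 3, 0 and 8 false calls. The simulated noise was independent between genes, so these false calls do not cover trends shared across genes. In the real data, a split of the control and clone 2 libraries that follows no label in full called 1560 genes. That split set the NTC libraries against the C-26 libraries, so it follows the codes in part and is no count of false calls.

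Genes at FPKM of 1 or more in at least 3 libraries were tested, 10783 in all. log2(FPKM + 1) was fitted for all 9 libraries together in limma 3.58.1 with a mean-variance trend (R 4.3.3), and p-values were adjusted by Benjamini-Hochberg over all tested genes, called below 0.05. F tests over the 3 groups of a labelling gave the number of genes that differ among them. Figures and checks used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

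Gene lists were written before the data were examined: literature targets of miR-204-5p, PI3K pathway, chemokines and cytokines, interferon, MHC class I, epithelial, mesenchymal, extracellular matrix and proteases, TGF-beta, G1/S, G2/M, p53, hypoxia, unfolded protein response, cholesterol synthesis, RNA silencing, immediate early, and markers of endothelial cells, fibroblasts and leukocytes. Symbols were matched to the table with older symbols allowed. Lists were tested with camera at its preset correlation of 0.01 and with an estimated one, and genes were also adjusted over the list alone.

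3′ UTRs, transcript length and GC content came from GENCODE M21 on GRCm38, the assembly of mm10, matched by Entrez ID with the longest 3′ UTR per gene (20351 genes, 10391 of them tested). Genes with the 8mer AAAGGGAA were compared with those lacking AAAGGG, beside the same comparison for permuted 8mers. The plan named 100 permutations, but 53 exist that lack part of the site, with 2 left out. Length and GC were corrected with natural splines of 4 degrees of freedom on the deviation of each library from the gene mean. Receptor genes were 1446 olfactory and vomeronasal receptors.

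The alternatives were a pseudocount of 0.1, no filter (20025 genes), quantile and median ratio scaling, array weights, fits with only the groups compared, each library left out, the block, the length and GC correction, the authors' quantile-normalized values, and the libraries titled clone 3 left out. Regroupings of the libraries gave the counts that arise without regard to the labels.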

Results

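RNA of 4T1 mouse mammary carcinoma cells was sequenced in 9 libraries, and each library carries 2 labels that cross. The titles name a control, clone 2 and clone 3, with 3 libraries each, and mark the clones with miR-204-5p. A further label gives its overexpression as 150-fold in clone 2 and 525-fold in clone 3 over control. The descriptions give each library of a title group a different code, NTC, C-20 or C-26, and the authors' deposited comparison table groups the libraries by code. The comparison headers of that table name test and control groups without a code. The group means identify NTC as the control of C-20 and of C-26. The labels thus attach raised miR-204-5p to the titles, while the deposited comparisons follow the codes, so both groupings are reported, with NTC and the control title as references. No combination of title and code was repeated. The spread in a fit by title thus includes differences between codes, and that in a fit by code differences between titles. With a block it is what remains after both labels, so no p-value rests on replicates of a combination. Nothing states that the libraries of a group came from separate cultures, so how far biological spread enters is unknown. The grouping, the gene filter, the gene lists and the tests were chosen before the data were examined.

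Libraries of 1 title resembled each other most: the median correlation of log2(FPKM + 1) was 0.975 within titles, 0.943 within codes and 0.936 where libraries shared neither label. The first principal component held 53.4% of the variance and set the libraries titled clone 3 apart (0.239 to 0.572, against −0.397 to −0.070 in the other 6). Of olfactory and vomeronasal receptor genes, known from sensory neurons, 9.20% and 5.95% were above 0 in the C-20 and C-26 libraries titled control. The share was 6.71% and 16.32% in those titled clone 2, and 0.97% to 3.39% in the other 5 libraries.

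**Figure D1:**
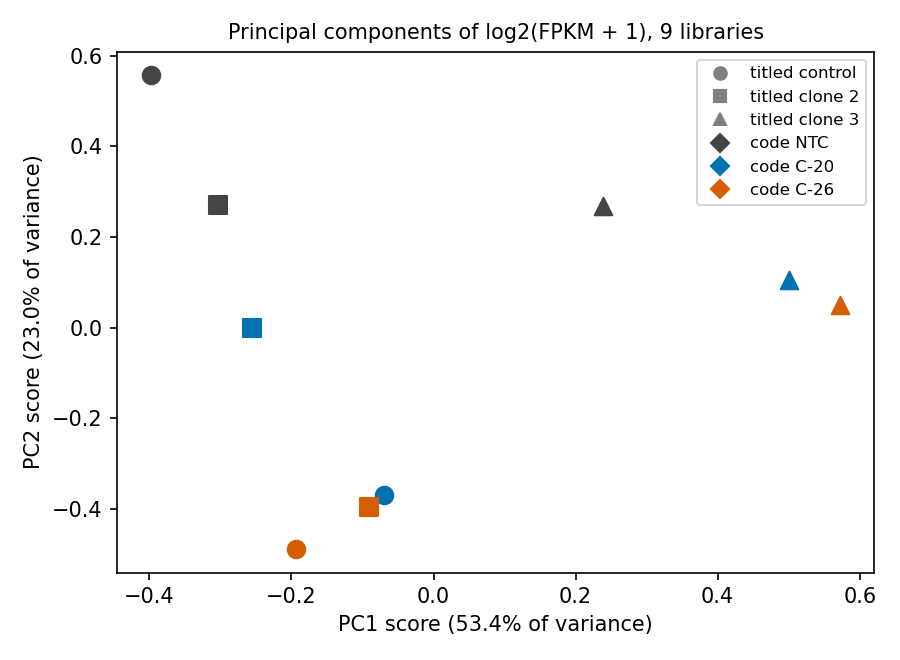
First principal component (53.4% of variance) against the second of log2(FPKM + 1), colored by code and shaped by title group. The libraries titled clone 3 lie at 0.239 to 0.572 on the first component and the other 6 below 0.

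**Figure D2:**
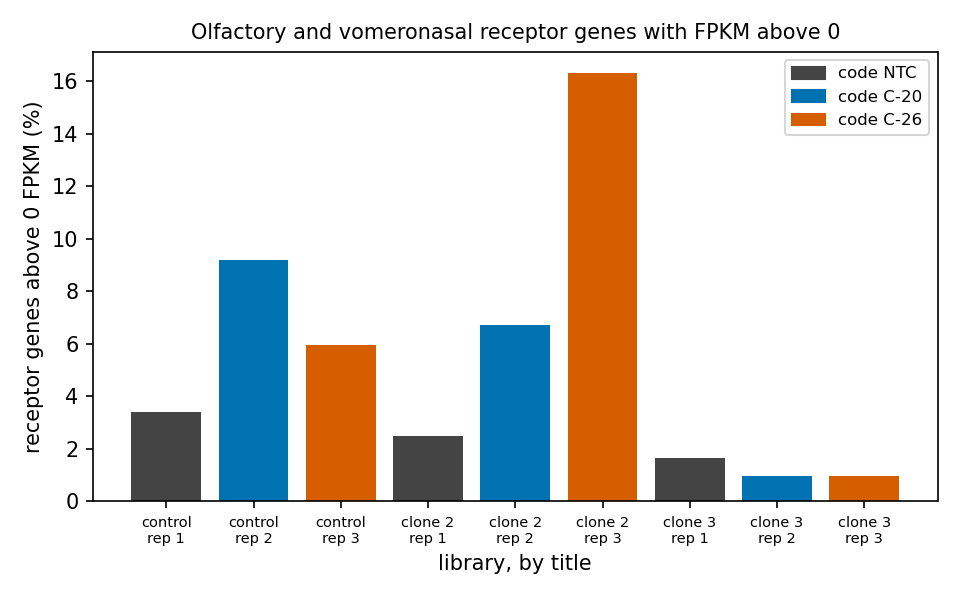
Percent of 1446 olfactory and vomeronasal receptor genes above 0 FPKM in each of the 9 libraries, by title group and code. The share was highest, at 16.32%, in the C-26 library titled clone 2 and lowest, at 0.97%, in the C-20 and C-26 libraries titled clone 3.

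The precursor gene Mir204 (mm10, chromosome 19, 22750605 to 22750672) was listed at 0 FPKM in all 9 libraries, and its host gene Trpm3 (chromosome 19, 22137797 to 22995410) reached at most 0.103 FPKM. Polyadenylated RNA reports mature miR-204-5p poorly, so neither gene shows which libraries overexpressed it. Pik3cb, a catalytic subunit of PI3K with an 8mer seed site in its 3′ UTR of 3059 nt (chromosome 9, 99038402 to 99140235), was lower in C-20 and C-26 than in NTC in 3 of 3 pairs of 1 title. The log2 changes were −0.45 in C-20 and −0.51 in C-26, neither passing (limma with Benjamini-Hochberg adjusted p = 0.6355 and 0.2292, and 0.1670 and 0.0650 with the title group as block). By title, Pik3cb differed from control by 0.22 in clone 2 and 0.10 in clone 3 (limma adjusted p = 0.8525 and 0.7892). Bcl2, an inhibitor of apoptosis and a literature target of miR-204-5p, was at 4.09 ± 0.767 FPKM in NTC, 4.4 ± 1.39 in C-20 and 4.86 ± 1.74 in C-26 (mean ± SD, n = 3). It was lower in clone 3 than in clone 2 by title (log2 −0.66 ± 0.18, limma adjusted p = 0.0299). That call was lost with length and GC correction (−0.28, 0.2536), and without clone 2 replicates 1, 2 and 3 (0.0517, 0.1127 and 0.0767) and clone 3 replicates 2 and 3 (0.1159 and 0.1158).

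Genes with an 8mer seed site of miR-204-5p (AAAGGGAA) in the 3′ UTR numbered 692, against 6765 genes without the core of the site. Their mean log2 change differed from that of the others by −0.201 in clone 3 against control, −0.056 in C-20 and −0.043 in C-26 against NTC, and 0.045 in clone 2 against control. Genes with 1 of 53 permuted 8mers gave medians of −0.248, −0.077, −0.062 and 0.038 for the same comparisons, so genes with the miR-204-5p site were not lower than genes with shuffled sites. With transcript length and GC content corrected, a step chosen after the data were seen, the difference turned to 0.084 in clone 3, 0.013 in C-20 and 0.002 in C-26. It was 0.047 in C-20 without clone 3 replicate 2 and 0.030 in C-26 without clone 3 replicate 3. The 22 tested literature targets of miR-204-5p held 0 genes higher and 6 lower in clone 3 against control (7 lower adjusted over the list alone), among them Sirt1 at log2 −1.67, Tgfbr1 at −1.40, Ap1s2 at −1.11 and Ap1s3 at −1.01. Camera did not call this list in clone 3 against control, and of all 10783 tested genes 802 were higher and 1418 lower there. With the same correction, Sirt1 kept its call (−1.21), Tgfbr1 lost it (−0.44) and Ap1s3 turned to 0.11. Ap1s2 turned to 0.81 and was called higher (limma adjusted p = 0.0059).

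Mgp, which encodes matrix Gla protein, an inhibitor of calcification, was at 75.4 ± 58 FPKM in C-26 and 2.34 ± 0.587 in NTC (mean ± SD, n = 3; log2 4.25; chromosome 6, 136872435 to 136875823). S100a16, a calcium-binding protein gene, was at 10.7 ± 2.37 against 1.71 ± 0.0953 FPKM (log2 2.09; chromosome 3, 90537254 to 90543151), and Eya2, a transcriptional coactivator, at 10.1 ± 1.81 against 1.76 ± 1.03. Igfbp7, a secreted binder of insulin-like growth factors, was at 5.94 ± 0.417 against 22.1 ± 4.74 FPKM (log2 −1.72; chromosome 5, 77349240 to 77408045). Without a block, limma with Benjamini-Hochberg adjustment called 13 genes higher and 2 lower in C-26 (1794 at raw p below 0.05). The higher genes were Mgp, S100a16, Eya2, Tmie, Lgals9, Eml1, Trib2, Lcp1, Sulf2, Plcd1, C1rl, Mir8099-1 and Mir8099-2, and the lower ones were Igfbp7 and Ecscr.

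**Figure D3:**
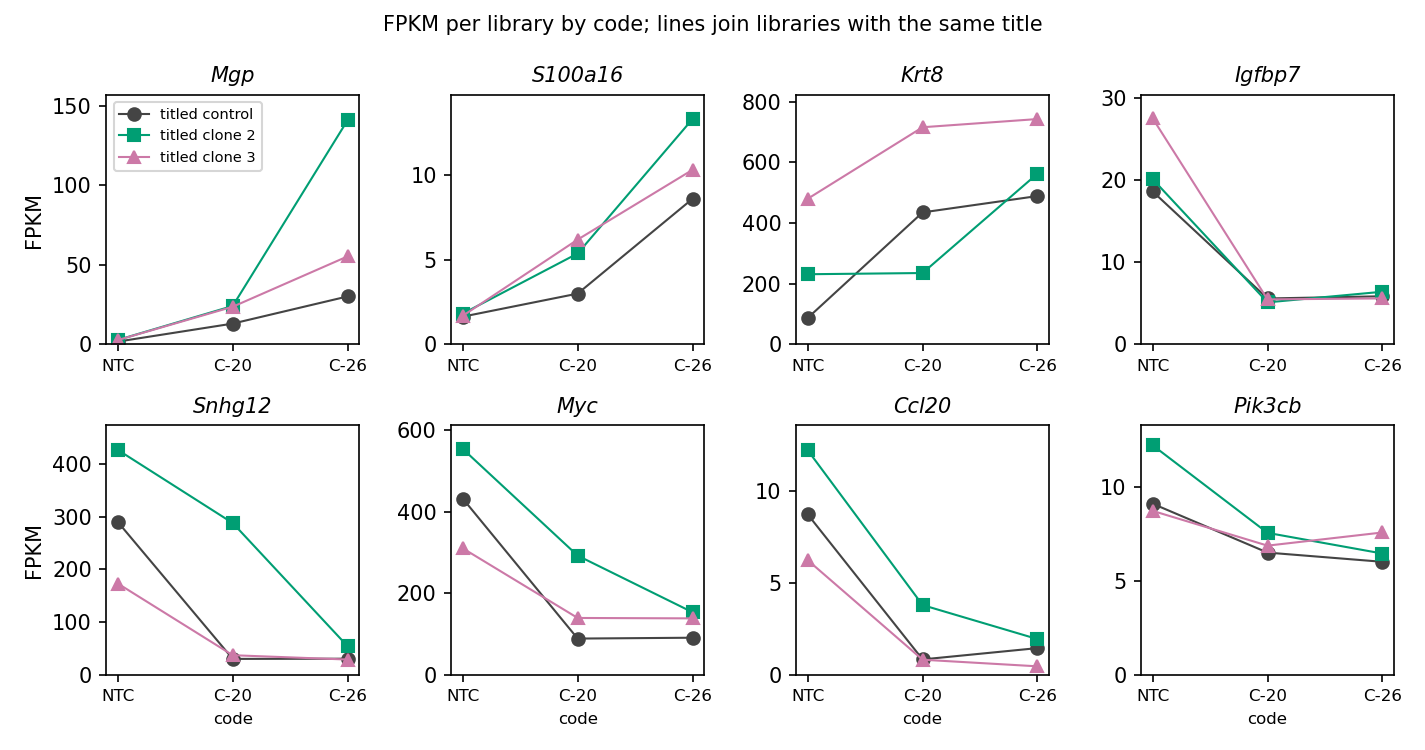
FPKM of single libraries by code for 8 genes, with lines joining libraries of 1 title. Mgp averaged 2.34 FPKM in NTC and 75.4 in C-26, and Igfbp7 22.1 and 5.94.

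With the title group as block, limma called 728 genes higher and 794 lower in C-26 than in NTC, and 1517 of these moved in 1 direction in all 3 pairs. Myc, the growth-promoting transcription factor, was at 127 ± 32.6 FPKM in C-26 and 432 ± 122 in NTC (log2 −1.75, limma adjusted p = 0.0076). Crip1, a LIM-domain protein gene, was at 472 ± 83.5 against 119 ± 113 FPKM (log2 2.36), and the mast cell protease gene Mcpt8 at 8.35 ± 2.77 against 0.991 ± 0.809 (2.27). Add2, Lypd3, Btc and Nptx1 rose by 2.26, 2.02, 2.00 and 1.98. Snhg12, a host gene of small nucleolar RNAs (chromosome 4, 132308678 to 132311024), was at 37.5 ± 14.1 against 297 ± 127 FPKM (log2 −2.92), and the chemokine gene Ccl20 at 1.28 ± 0.756 against 9.05 ± 3.02 (log2 −2.16). Cox6a2, Acot2, Angptl6, Soat2, Cdsn, Plk2, Stbd1 and Gadd45a stood at log2 −2.71, −2.55, −2.32, −2.22, −2.11, −1.99, −1.96 and −1.91. Mgp, S100a16, Eya2, Tmie, Mcpt8, Add2, Nptx1 and Ccl20 kept their calls in the blocked fit without each of the 9 libraries in turn. Of 83 genes followed in this fit, which include Pik3cb and Bcl2 without a call, 73 lost theirs without clone 2 replicate 3 and 50 without clone 2 replicate 1.

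Interferon-stimulated genes were higher as a group in C-26: 27 of 28 tested were positive, with a median log2 change of 0.63, and camera called the list (adjusted p = 2.2e-07, but 0.7356 with an estimated correlation). With the block 8 passed over all genes and 19 over the list alone, none of them lower, with Oas1a at 1.15, Igtp at 1.11, Sp100 at 1.10 and Stat2 at 1.05 (6.43 ± 0.896 against 2.71 ± 1.25 FPKM). Cholesterol synthesis genes were positive in 24 of 24, median 0.69, with 5 higher and 0 lower (8 and 0 over the list alone), including Tm7sf2 at 1.40, Dhcr7 at 1.15, Mvd at 1.02 and Fdft1 at 0.84 (camera adjusted p = 0.0019, 0.7356 with an estimated correlation). The unfolded protein response list fell, with 1 gene higher and 6 lower (3 and 12 over the list alone) and a median of −0.51 (camera adjusted p = 0.0043, 0.7356 with an estimated correlation). Its stress-response members Ddit3 (20.1 ± 4.71 against 68.5 ± 26 FPKM) and Trib3 (60.8 ± 16.7 against 190 ± 24.7) both stood at log2 −1.66, Ppp1r15a at −1.62 and Aldh1l2 at −1.61. G2/M genes had a median of 0.46 with 1 higher, Kif2c at 0.75, and 0 over the list alone (camera adjusted p = 6.5e-04, 0.7356 with an estimated correlation). The epithelial and immediate early lists also passed camera (both adjusted p = 0.0374, 0.7356 with an estimated correlation). Krt8 (598 ± 131 against 266 ± 199 FPKM), Krt19 and Jup stood at 1.47, 1.46 and 1.34 and Cldn3 at −1.07, while Hspb1 stood at 1.52, Zfp36 at 1.45 and Egr3 at 0.99.

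The other 12 lists were not called in C-26 by camera, although single members passed limma with the block. Of all 10783 tested genes 728 were higher and 794 lower in that fit. The G1/S, hypoxia and miR-204-5p target lists did not exceed that share. Chemokines and cytokines held 5 higher and 7 lower of 21 (6 and 8 over the list alone), with the fractalkine gene Cx3cl1 at log2 1.63 (26.7 ± 3.56 against 8.39 ± 3.64 FPKM), Vegfc at −1.46 and Vegfa at −1.27. Extracellular matrix and protease genes held 5 higher and 3 lower of 30 (12 and 6), with Spp1 at 1.83, Mmp10 at 1.57, Plat at 1.37 and Adamts1 at −1.33. TGF-beta genes held 5 higher and 3 lower of 29 (7 and 8), with Id2 at 1.75, Tgfb3 at 1.05, Ltbp3 at 1.03 and Tgfbr3 at 1.00. PI3K pathway genes held 4 higher and 2 lower of 37 (6 and 3), with Sgk1 at 1.79 (84.2 ± 17.7 against 24.2 ± 7.92 FPKM), Erbb3 at 0.94, Rheb at −0.89 and Gsk3b at −0.72. Their median was −0.01 and their mean 0.10. MHC class I genes held 4 higher and 0 lower of 23 (4 and 0), H2-T22 at 1.46, Psme1 at 1.18, Calr at 0.99 and Psmb9 at 0.98. G1/S genes held 4 higher and 0 lower of 43 (0 and 0), Pold1 at 1.05, Pola2 at 0.74, Ccnd1 at 0.73 and Mcm2 at 0.69. With length and GC corrected, 80 of 82 named genes of this fit stayed the same and 2 became weaker, among them Mcm2 (0.54, limma adjusted p = 0.0761). The p53 list held 3 higher and 3 lower of 23 (4 and 5), with Trp53 at −0.94, Perp at 0.86 and Ephx1 at 0.80. The hypoxia list held 2 and 3 of 38 (2 and 3), with Pfkfb4 at 0.97, Egln3 at 0.95 and Ero1l at −0.73. RNA silencing genes held 1 higher and 2 lower of 17 (1 and 2), Mov10 at 1.13, Xpo5 at −0.82 and Pan3 at −0.62. Mesenchymal genes held 1 and 1 of 13 (2 and 2), Itgb3 at 1.30 and Zeb2 at −0.80. Literature targets of miR-204-5p held 2 higher and 1 lower of 22 (4 and 2), Ezr at 0.84, Tgfbr2 at 0.77 and Sox4 at −0.92. Of markers of other cell types, 3 of 12 endothelial, 2 of 14 fibroblast and 2 of 22 leukocyte genes were expressed enough to test, with list medians of 0.111, 0.0223 and 0.0328 FPKM. The most abundant were Egfl7 at 16.2, Fbln2 at 86.4 and Cd68 at 7.15 FPKM, and Flt1, Pdgfra and Cd68 were higher in C-26 by log2 0.79, 1.20 and 0.61.

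The calls in C-26 against NTC leaned on single libraries: 15 without a block became 3, 9 and 3 without control replicates 1, 2 and 3, 2, 9 and 3 without those of clone 2, and 3, 8 and 19 without those of clone 3. With the block, 1522 became 309 without control replicate 3, 190 and 21 without clone 2 replicates 1 and 3, and 545 and 983 without clone 3 replicates 2 and 3; it was 115 with no filter and 303 without the libraries titled clone 3. The share of higher genes with the block, 47.8%, was 71.9% without the libraries titled clone 3 and 76.2% without clone 2 replicate 3. Interferon, G2/M and unfolded protein response genes kept their list call without each library in turn in the fit without a block. Cholesterol genes lost it without clone 3 replicate 3 (camera adjusted p = 0.2083), epithelial genes without control replicate 1 (0.4102), clone 2 replicates 2 and 3 (0.0506 and 0.0618) and clone 3 replicate 3 (0.2083). Immediate early genes lost it without control replicate 3 (0.3325) and clone 3 replicate 1 (0.2288). With length and GC corrected the epithelial and immediate early lists also lost their calls (both 0.1628).

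In C-20, Igfbp7 was at 5.37 ± 0.248 FPKM against 22.1 ± 4.74 in NTC (mean ± SD, n = 3; log2 −1.84), and Ecscr, an endothelial signaling regulator, at 0.0619 ± 0.0427 against 1.69 ± 0.213 (log2 −1.34). These were the 2 genes that limma with Benjamini-Hochberg adjustment called without a block (both adjusted p = 0.0302), with 0 higher and 834 at raw p below 0.05. With the title group as block, limma called 19 genes higher and 14 lower, a share of 57.6% higher that was 38.5% on the authors' quantile-normalized values. The count was 10 with no filter, 3 of them higher, and 0 without the libraries titled clone 3. The surface immunoglobulin gene Igsf8 was at 109 ± 24.4 against 31.8 ± 5.26 FPKM (log2 1.73, limma adjusted p = 0.0039) and Mgp at 20.2 ± 6.24 against 2.34 ± 0.587 (2.64, 0.0055). Xlr, Mcpt8, Eya2, Id2, Gsta4, Nptx1, Akr1c12 and Gsn stood at log2 1.95, 1.76, 1.66, 1.57, 1.56, 1.55, 1.38 and 1.32. Txnip, which restrains glucose uptake and thioredoxin, was at 16.5 ± 4.66 against 85.7 ± 55.4 FPKM (log2 −2.16, limma adjusted p = 0.0055), and Ccl20 at 1.81 ± 1.71 against 9.05 ± 3.02 (−1.96). Edn1, Ctsw, Nnmt, Pdgfb, Ank2, Birc3 and Fgf21 stood at log2 −1.60, −1.59, −1.40, −1.14, −1.10, −1.05 and −1.05. Txnip kept its call in the blocked fit without each library in turn.

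Camera called 7 lists in C-20 against NTC, and 0 with an estimated correlation. Cholesterol synthesis genes had a median log2 change of 0.67 (camera adjusted p = 2.8e-04, 0.8123 with an estimated correlation), with 0 members passing over all genes and 3 higher over the list alone in the blocked fit. Extracellular matrix and protease genes had a median of 0.35 (0.0038), with 10 higher and 1 lower over the list alone, and the unfolded protein response list −0.44 (0.0089), with 2 higher and 8 lower over the list alone. G2/M, immediate early, interferon and epithelial genes had medians of 0.26, 0.45, 0.23 and 0.21 (camera adjusted p = 0.0078, 0.0149, 0.0092 and 0.0262, and 0.8123 with an estimated correlation for each list). TGF-beta genes, not called, had a median of −0.24 and a mean of 0.02, with 1 higher over all genes, Id2. The blocked count of 33 became 111 and 13 without control replicates 1 and 2, 3 and 66 without clone 2 replicates 1 and 2, and 1 without clone 3 replicate 2. There Igsf8 (adjusted p = 0.0572), Igfbp7 (0.0880) and Ccl20 (0.0880) also lost their calls, as Ccl20 did without clone 2 replicate 1 (0.0532). The count of 2 without a block fell to 0 without any library but clone 3 replicate 3. Each of the 7 lists lost its call (camera adjusted p in brackets) without some library: cholesterol genes without clone 3 replicate 2 (0.0789), and the unfolded protein response list without control replicate 2 (0.1380). G2/M genes lost theirs without control replicates 1 and 2 (0.2704 and 0.1621), extracellular matrix genes without control replicate 1 (0.1857) and clone 2 replicate 2 (0.0667), and immediate early genes without control replicate 2 (0.6621) and clone 3 replicate 1 (0.2467). Interferon genes did so without control replicate 2 (0.0920), clone 2 replicates 1 and 2 (0.1179 and 0.1216) and clone 3 replicate 1 (0.1229), and epithelial genes without control replicate 1 (0.6886), clone 2 replicate 2 (0.1721) and clone 3 replicate 2 (0.1135). With length and GC corrected, the epithelial (0.1910) and immediate early lists (0.1607) lost their calls.

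Of the 33 genes called in C-20 with the block, 18 of 19 higher and 13 of 14 lower were called in C-26 too, out of its 1522. Independent lists would share 1.28 and 1.03, but both comparisons use the same NTC libraries, so part of the excess may come from them. The log2 changes of the 2 codes correlated at 0.91, against 0.50 in simulated data with no effect and the same NTC libraries. The simulated noise was independent between genes, which fixes its correlation near 0.50. Trends shared across genes were left out, so the gap does not show movement beyond the shared NTC libraries. For clone 2 and clone 3 against control the data gave 0.29, where the simulation also gave 0.50. Against each other, C-26 and C-20 differed in Mir8099-1 and Mir8099-2 alone by limma with Benjamini-Hochberg adjustment (both adjusted p = 3.1e-04, 99 genes at raw p below 0.05). These were at 3.35 ± 0.191 FPKM in C-26 (n = 3) and listed at 0 in the other 6 libraries. Their values are identical in every library although they lie at 2 loci (chromosome 3, 95139060 to 95139186, and chromosome 12, 93927338 to 93927464), so the source locus is uncertain. C1rl, a complement protease-like gene, was at 1.82 ± 0.265 in C-26 and 0.504 ± 0.021 FPKM in C-20, which did not pass (log2 0.90, limma adjusted p = 0.6134). Interferon-stimulated genes were positive in 28 of 28 with a median of 0.36, although 0 passed over all genes and 1 over the list alone with the block (camera adjusted p = 2.8e-13, 0.7417 with an estimated correlation). MHC class I, G1/S and G2/M genes (camera adjusted p = 0.0101 each) and hypoxia genes (0.0309) were called higher too, with medians of 0.12, 0.14, 0.17 and 0.07 (0.7417, 0.9786, 0.9784 and 0.9784 with an estimated correlation). Other splits of these libraries, which follow no code, called up to 9 lists against 5 here. The joint effect of C-20 and C-26 differed between clone 3 and the pooled other title groups in 0 genes by an interaction test (744 at raw p below 0.05). Differences between control and clone 2, or for each code alone, were not tested.

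Fos, an immediate early transcription factor, was at 1.3 ± 0.34 FPKM in the libraries titled clone 3 and 129 ± 79.5 in those titled control (mean ± SD, n = 3; log2 −5.54 ± 0.51, limma with Benjamini-Hochberg adjusted p = 1.6e-04; chromosome 12, 85473890 to 85477274). Its relative Fosb was at 1.66 ± 0.562 against 61.8 ± 33.9. Mki67, a proliferation marker, was at 8.69 ± 3.72 against 61.8 ± 33 (log2 −2.57), and the G2/M genes Kif20b, Cenpf, Cenpe and Bub1 stood at −3.52, −2.98, −2.91 and −1.94. Fgfbp1, a secreted carrier of fibroblast growth factors, was at 49.4 ± 7.89 against 7.43 ± 4.23 FPKM (log2 2.68 ± 0.34, limma adjusted p = 5.8e-04; chromosome 5, 43978858 to 43981828). The metastasis-linked gene S100a4 was at 416 ± 83 against 120 ± 22.3 FPKM (1.79 ± 0.31, limma adjusted p = 0.0032), and the gelatinase gene Mmp9 at 33.2 ± 1.71 against 11.4 ± 5.8 (1.56). In all, 802 genes were higher and 1418 lower, of which 2210 moved in 1 direction in the 3 pairs of equal replicate number. Fos, Fosb, Fgfbp1, S100a4, Mmp9, Krt7, Mki67, Kif20b, Rock1, Nemf, Shmt2 and Arhgap5 kept their calls without each library in turn.

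Cholesterol synthesis genes were higher in clone 3 than in control, with 7 higher and 0 lower of 24 (9 and 0 over the list alone) and a median log2 change of 1.02 (camera adjusted p = 0.0013, 0.7869 with an estimated correlation). Fdps was at 291 ± 81.3 against 98.2 ± 54.6 FPKM (log2 1.70). Immediate early genes held 0 higher and 7 lower, median −0.48, with Dusp1 at −2.43 and Egr1 at −2.30. Interferon genes held 0 and 6 (0 and 7), median −0.47, with Samd9l at −1.67 and Ifit2 at −1.30. Epithelial genes held 7 higher and 1 lower (10 and 1), median 0.41, with Krt14 at 1.57, Lamb3 at 1.51 and Krt7 at 1.28. Mesenchymal genes held 5 and 1 (6 and 1), median 0.58. These 4 lists passed camera at an adjusted p of 0.0154, and extracellular matrix and protease genes at 0.0284 with 6 higher and 0 lower (all 0.7869 with an estimated correlation). Interferon genes lost their call without control replicate 3 (0.0973) and clone 3 replicate 1 (0.0867), and immediate early genes without control replicate 2 (0.0651) and clone 3 replicate 1 (0.0572). Epithelial genes lost theirs without control replicate 1 (0.0513), and extracellular matrix genes without control replicate 1 (0.1736) and clone 3 replicate 2 (0.0570). G2/M genes held 5 higher and 11 lower (5 and 12), with a median of 0.03 and a mean of −0.27. Members of lists not called included Ccne2 at −2.62, Pik3c2a at −1.93, Rrm2b at −1.77, Bmpr2 at −1.50, Shmt2 at 1.24 and Pkm at 0.82.

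Changes in clone 3 followed base composition: the median log2 change was −0.73 in the bin of genes with the lowest GC content and 0.40 in the highest of 5 bins. With length and GC corrected, a step chosen after the data were seen, Fos (−5.82), Fosb (−4.73), Fgfbp1 (2.67), S100a4 (1.72), Mmp9 (1.20), Krt7 (1.05), Mki67 (−2.29), Cenpf (−2.29), Kif20b (−2.28), Rock1 (−2.29) and Nemf (−2.68) kept their calls. Fdps (1.35, limma adjusted p = 0.0729), Lamb3 (1.21, 0.0712), Pkm (0.40, 0.1092), Ccne2 (−0.89, 0.0627), Bub1 (−1.08, 0.0556), Pik3c2a (−0.58, 0.0651), Bmpr2 (−0.44, 0.0902), Samd9l (−0.33) and Ifit2 (−0.59) lost theirs. Of all 79 named genes of this comparison, 35 stayed the same, 41 became weaker and 3 changed sign. Cholesterol, interferon and immediate early genes remained called by camera, while epithelial (0.2178), mesenchymal (0.1017) and extracellular matrix genes (0.0522) did not. Title group and leading number of the description run together, so a batch cannot be told from the clone. The count of 2220 became 1364 without control replicate 3, and 1057 and 1011 without clone 3 replicates 2 and 3, where the share of higher genes went from 36.1% to 16.2% and 20.1%.

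**Figure D4:**
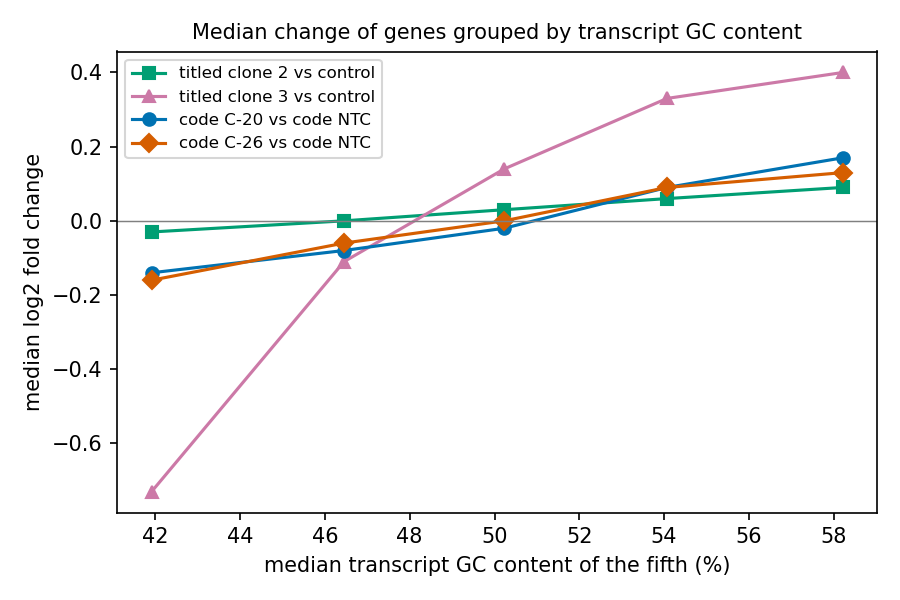
Median log2 fold change of the tested genes in 5 bins of transcript GC content (percent), for clone 2 and clone 3 against control and C-20 and C-26 against NTC. In clone 3 against control the median ran from −0.73 to 0.40, and in C-26 against NTC from −0.16 to 0.13.

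In the libraries titled clone 2, limma with Benjamini-Hochberg adjustment called 0 genes against control (949 at raw p below 0.05, smallest adjusted p = 0.1536). The smallest was that of Tigit, an inhibitory receptor of lymphocytes, at 32 ± 3.09 against 10.5 ± 2.59 FPKM (mean ± SD, n = 3; log2 1.54 ± 0.20). Smox, Masp1, Bcl6 and Fosb came next at log2 1.04, 1.31, 1.09 and −2.49 (all adjusted p = 0.2051). G1/S genes were lower as a group, 1 of 43 being positive, with a median of −0.49 and 13 lower over the list alone (camera adjusted p = 6.5e-18, 0.2499 with an estimated correlation). Extracellular matrix and protease genes had a median of 0.42 (2.5e-08, 0.2499) with 5 higher over the list alone, cholesterol genes −0.47 (1.1e-05, 0.5289) and immediate early genes −0.46 (9.1e-05, 0.5289). Epithelial, mesenchymal, PI3K and TGF-beta genes had medians of 0.28, 0.34, 0.18 and 0.27 (camera adjusted p = 1.3e-04, 0.0077, 0.0112 and 0.0496, and 0.4863, 0.2499, 0.5289 and 0.4863 with an estimated correlation). The count of 0 became 13 without control replicate 1, 2 without clone 2 replicate 1 and 1 without clone 3 replicate 3. Cholesterol genes lost their list call without control replicate 2 (0.0904), mesenchymal genes without clone 2 replicate 3 (0.0926), and PI3K genes without control replicate 1 (0.1700) and clone 2 replicate 3 (0.0543). TGF-beta genes lost theirs without control replicates 1, 2 and 3 (0.0855, 0.0806 and 0.1425) and clone 2 replicates 2 and 3 (0.0718 and 0.0569). With length and GC corrected, the PI3K (0.2932) and TGF-beta lists (0.1440) lost their calls.

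Cholesterol synthesis genes were also higher in clone 3 than in clone 2: 15 of 24 were higher and 0 lower (18 and 0 over the list alone), with a median log2 change of 1.37 (camera adjusted p = 7.7e-09, 0.9536 with an estimated correlation). Acat2 was at 91 ± 23 against 22 ± 11.9 FPKM (mean ± SD, n = 3; log2 2.09 ± 0.55, limma with Benjamini-Hochberg adjusted p = 0.0271), and Fdps, Mvd, Fdft1, Mvk, Acat3 and Cyp51 stood at log2 1.96, 1.86, 1.80, 1.78, 1.77 and 1.72. G1/S genes held 19 higher and 2 lower of 43 (30 and 3), median 0.67, with Cdc6 at 1.33 and Ung at 1.27 (camera adjusted p = 1.2e-07, 0.9536 with an estimated correlation). Literature targets of miR-204-5p held 0 higher and 8 lower (2 and 12), median −0.45 (camera adjusted p = 0.0195, 0.9536 with an estimated correlation). Of these targets, Tgfbr1 (−0.29, limma adjusted p = 0.2828) and Bcl2 (−0.28, 0.2536) lost their calls with length and GC corrected and Ap1s2 turned to 0.69 (0.0140). Lists of this comparison were not tested without single libraries, and other splits of its libraries called up to 6 lists against 3 here. Arhgap5, Esf1, Rock1, Nemf, Fos and Kif20b stood at log2 −3.68, −3.58, −3.41, −3.21, −3.21 and −3.14. Ptgs2 and the secreted factors Tslp, Areg, Bdnf and Lcn2 stood at −1.97, −1.46, −1.46, −1.43 and −1.21. In all 650 genes were higher and 1380 lower, a count of 2030 that became 3443 without control replicate 1, 1181 and 865 without clone 2 replicates 1 and 2, and 835 without clone 3 replicate 2 or 3. The share of higher genes, 32.0%, was unstable: it was 48.4% after length and GC correction, and 7.9% and 8.3% without clone 2 replicate 2 and clone 3 replicate 2. The median change ran from −0.72 to 0.30 across the GC bins. With length and GC corrected, Acat2 (1.93, limma adjusted p = 0.0609), Mvk (1.42, 0.0706), Ung (0.94, 0.1769), Ptgs2 (−0.92, 0.1531), Bdnf (−0.54, 0.1532) and Tslp (−0.51, 0.1122) lost their calls, and Arhgap5 kept its call at −1.31. Of 73 named genes, 34 stayed the same, 35 became weaker and 4 changed sign.

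The authors' deposited comparison table, limited to genes above 0 in all 9 libraries, calls 0 of them at its adjusted p-value in any of its 3 comparisons of codes. Its raw p-value was below 0.05 in 569 genes for C-20 over NTC, 1189 for C-26 over NTC and 273 for C-20 over C-26, with smallest adjusted p-values of 0.911, 0.189 and 1. Its signed folds for Mgp were 5.89 in C-20 and 18.8 in C-26, for Igfbp7 −3.56 and −3.3, for Ccl20 −3.92 and −4.85, for Snhg12 −3.75 and −7.16, and for Pik3cb −1.39 and −1.47. At 2-fold or more it holds 237 genes higher and 156 lower in C-26 and 90 and 63 in C-20.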

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

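The patterns below were noticed in the data, and what each explanation predicts was written down before its test was run, except where said. The tests of quantile scaling, of the leading number and of base composition as the whole cause were chosen after the result was seen. The length and GC correction was chosen after the trend with GC content had been noticed.

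Of 1446 olfactory and vomeronasal receptor genes, 9.20% and 5.95% were above 0 in the C-20 and C-26 libraries titled control and 6.71% and 16.32% in those titled clone 2. Sequencing depth did not track the number of genes above 0 (Spearman rho 0.02 with relative depth, exact p = 0.982). Mean FPKM of the receptor genes did not set the 4 libraries apart. It was 0.008043 in the NTC library titled control and 0.006364 in the C-20 library titled clone 2. By share above 0, the lowest of the 4 was 1.76 times the highest of the other 5, so reads from genomic DNA or unspliced RNA may have spread over silent genes in the 4 libraries. They were not the whole source of 218 genes called higher in C-26 without the libraries titled clone 3: their medians were 1.42 and 1.31 in the number 1 and 2 pairs and still 0.60 in the number 4 pair, which lacks the signal, although the drop leaves room for a part; of 85 genes called lower, 84 were lower in that pair too (median −0.61). In the first test the median of that pair was 0.49 against a bound of 0.5, and a margin of the bootstrap standard error of 0.01 was added after the value had been seen and had read as fitting, so it is left open for the 728 genes called higher with the block.

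The libraries titled clone 3 may stand apart because of base composition in part. Of the genes with a known length and GC content, 2181 were called against control before correction and 868 after. In both fits 536 were called in the same direction, so the fitted trend was not the whole cause of the calls. Whether the correction left part of such a trend was not tested. Scaling did not account for clone 3 standing apart, since 2168 genes were called after quantile normalization. Nor did a few abundant genes, since the share of the top 10 differed by 0.937 percentage points. A batch marked by the leading number stays open, because 0 libraries part number and title. For the calls in C-26 with the block a trend with base composition was not the main cause: 1977 genes were called after the correction, and 1414 of the 1615 called before it were called in the same direction.

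The labels attach miR-204-5p to the titles, while the group means of the authors' table identify NTC as control of C-20 and C-26. Which labelling follows raised miR-204-5p in the expression values stays open. Genes with an 8mer site differed by 0.045 in clone 2 against control and by −0.043 in C-26 against NTC, and neither lay below the median of permuted sites. The written prediction counted against a labelling if neither of its comparisons lay below that median, which holds for both labellings. The test added a margin of the standard deviation of the permuted sites, which was not part of that prediction. Neither labelling was above the median by more than this margin in both of its comparisons, so neither was ruled out. Beside 3′ UTR length the term for a site was −0.006 in C-26 and −0.012 in C-20, so longer 3′ UTRs stay open as a source of the lower values. With transcript length and GC content corrected the values were not lower (0.002 in C-26 and 0.013 in C-20).

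Regroupings of the 9 libraries into 3 groups spoke against chance for the title groups, where 2 of 100 gave as many as 2070 genes (highest other 5059) and 1 of 36 with the block (3451, highest other 2430). For the codes with the block the real labelling ranked first of 36, but close to the next (490 genes, highest other 432). That count became 58, 14, 24 and 24 without control replicate 3, clone 2 replicates 1 and 3 and clone 3 replicate 2, 280 without clone 3 replicate 3, and 26 with no filter. Chance is therefore not firmly excluded for the codes with the block, and not excluded without it, at 11 of 100 (5 genes, highest other 5059). The split that gave 5059 joined control replicate 1 with clone 2 replicates 1 and 2, which no label groups. Among the libraries titled control and clone 2, that split parted NTC from C-26 and so follows the codes in part. It and the next highest other splits without the block (1854, 1566 and 1566) kept the libraries titled clone 3 together, so that result speaks for clone 3 standing apart and not for a difference of clone 2 from control.

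Comparisons of 6 libraries have 10 splits, or 4 with the block, too few to exclude chance. Genes called were 0 in clone 2 against control (10 splits as many, highest other 1560), 2220 in clone 3 (1, 0), 2030 in clone 3 against clone 2 (1, highest other 1), 2 in C-20 (2, 38), 15 in C-26 (1, highest other 1) and 2 in C-26 against C-20 (1, highest other 1). With the block 33 were called in C-20 (1 split, highest other 0), 1522 in C-26 (1, 0) and 2 in C-26 against C-20 (1, highest other 1). Lists called were 8 in clone 2 (2 splits as many, highest other 8), 6 in clone 3 (3, 6), 7 in C-20 (3, 7) and 6 in C-26 (4, 8). They were 5 in C-26 against C-20 (highest other 9) and 3 in clone 3 against clone 2 (highest other 6). Camera at its preset correlation thus called as many lists on some splits that follow no label, so its list p-values do not exclude chance. Genes with an 8mer site differed by 0.045 in clone 2 (1 split as far from 0, highest other 0.044), −0.201 in clone 3 (1, 0.139), −0.056 in C-20 (7, 0.183) and −0.043 in C-26 (6, 0.128).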

How the results depend on the processing

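Most alternatives were listed before the data were examined. The length and GC correction, the authors' quantile-normalized values, the alternatives of the blocked fits and the fits without the libraries titled clone 3 were chosen after the data were seen. Of the values of named genes over all alternatives, 4088 stayed the same, 1113 became weaker, 39 stronger and 22 changed sign. For the results below that changed, the cause was not tested.

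With the replicate number as block, title comparisons gave 3 genes for clone 2 and 3330 for clone 3 against control and 3176 for clone 3 against clone 2, and 3451 genes differed among title groups. The number did not pair all libraries: the NTC and C-26 pairs correlated at 0.266 to 0.562, the C-20 pairs at −0.235, 0.207 and 0.075, and 7 of 9 libraries matched best with their own number. With the title group as block, codes gave 33 genes for C-20 and 1522 for C-26 against NTC, and 490 differed among codes.

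With only the 2 groups compared in the fit, counts were 1 for clone 2 against control, 0 for C-20 and 2 for C-26 against NTC, and 830 for C-26 with the block. Array weights gave 4142, 4493 and 6966 genes for clone 2 and clone 3 against control and clone 3 against clone 2, and 574, 4034 and 98 for C-20 and C-26 against NTC and C-26 against C-20 (1710, 4902 and 30 with the block). Bcl2 in C-20 turned to −0.04. Such weights also gave up to 8633 genes on splits that follow no label, so these counts are not reliable.

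A pseudocount of 0.1 gave 1 gene for C-20 and 298 differing among codes with the block. With no filter, counts were 4 for C-20, 27 for C-26, 4 for C-26 against C-20 and 18 among codes, and with the block 10 for C-20, 115 for C-26 and 26 among codes. Median ratio scaling gave 99 for C-20 with the block. Quantile normalization turned Pik3cb to 0.05 in clone 3 against clone 2. On the authors' quantile-normalized values counts were 11 for C-20, 72 for C-26, 0 for C-26 against C-20 and 20 among codes, and with the block 65 for C-20, 1 for C-26 against C-20 and 217 among codes. The share of higher genes in C-26 went from 86.7% to 68.1%. Mir8099-1 and Mir8099-2, the genes called in C-26 against C-20, are neither in that table nor among the genes with a known length and GC content, so the counts of that comparison under these alternatives are no test of them.

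Length and GC correction gave 868 genes for clone 3 against control, 907 for clone 3 against clone 2, 857 among title groups, 123 for C-26, 0 for C-26 against C-20 and 20 among codes. With the block it gave 126 for C-20, 1977 for C-26, 0 for C-26 against C-20 and 630 among codes, and it left 3 lists called in clone 3 against control. It reversed Ap1s2 (0.81), Ap1s3 (0.11) and Trp53inp1 (0.06) in clone 3 against control, and Ap1s2 (0.69), Ccne2 (0.20), Bmpr1a (0.04) and Pik3cb (0.28) in clone 3 against clone 2. It also turned the difference of genes with an 8mer site to 0.084 in clone 3, 0.013 in C-20 and 0.002 in C-26. Leaving out the libraries titled clone 3 gave 0 genes for C-20 and 4 for C-26, and 0 and 303 with the block. An estimated correlation left 0 lists called in clone 2 and clone 3 against control and in C-20 and C-26 against NTC.

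Without each library in turn, counts ran from 0 to 13 for clone 2 and 1011 to 2707 for clone 3 against control, 835 to 3443 for clone 3 against clone 2 and 740 to 3312 among title groups. For C-20 they ran from 0 to 2, for C-26 2 to 19, for C-26 against C-20 2 to 2 and among codes 2 to 6; with the block 1 to 111, 21 to 1809, 2 to 9 and 14 to 602. Lists called ran from 7 to 9 in clone 2, 4 to 7 in clone 3, 3 to 7 in C-20 and 4 to 8 in C-26. Genes with an 8mer site differed by 0.030 to 0.061, −0.244 to −0.161, −0.132 to 0.047 and −0.090 to 0.030 in the same order. Pik3cb changed sign, running from −0.02 to 0.39 in clone 2, −0.00 to 0.26 in clone 3, −0.29 to 0.12 in clone 3 against clone 2 and −0.14 to 0.01 in C-26 against C-20 (−0.18 to 0.06 with the block). Bcl2 did so from −0.11 to 0.27 in C-20 (−0.08 to 0.25 with the block), −0.00 to 0.44 in C-26 and −0.11 to 0.38 in C-26 against C-20 (−0.02 to 0.25 with the block). Other negative values of Bcl2 were −0.01 in C-20, and −0.00 and −0.06 in C-26 against C-20.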

Other observations

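These observations were made after the results were seen, and the tests they name are those given above with their time of choice.

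The labels attach miR-204-5p, at 150-fold and 525-fold over control, to the titles clone 2 and clone 3, yet the authors' deposited comparison table groups by code. Its group means identify NTC as the control of C-20 and of C-26.

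C-20 and C-26 moved together against NTC, with a correlation of log2 changes of 0.91 against 0.50 in simulated data that share the NTC libraries and hold no effect. That simulation drew independent noise for each gene. It leaves out trends that libraries share across genes, so it sets no bound on the correlation. The covariance exceeded that of the simulation by 0.141 with the block and 0.106 without. Candidate explanations are an effect that both codes share, a difference of the NTC libraries alone, or in part the signal in silent genes, which was not the whole source of the genes called in C-26 without the libraries titled clone 3 (0.60 in the number 4 pair). By share of receptor genes above 0, that signal was higher in the C-20 and C-26 libraries of control and clone 2. The lowest share there was 1.76 times the highest of the other 5 libraries. Mean FPKM of receptor genes did not part them, at 0.008043 in the NTC library titled control and 0.006364 in the C-20 library titled clone 2. The fitted trend with base composition did not account for the correlation of the codes. After length and GC correction, tested after the result was seen, the correlation was 0.92 and the covariance 0.147. Simulated data gave 0.50 and 0.015 with the block, which again set no bound. The corrected values thus do not show movement beyond the shared NTC libraries. Changes of clone 2 and clone 3 against control correlated at 0.29 against 0.50 in simulated data, with a covariance that exceeded the simulated one by 0.028 in the fit without a block.

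Mgp, S100a16, Eya2 and Tmie rose and Ccl20 fell in C-26 whichever library was left out of the blocked fit, and Fos, Fosb, Fgfbp1 and S100a4 kept their calls in clone 3 in the same way and after length and GC correction. Pik3cb, with an 8mer site, was lower in both codes in 3 of 3 pairs without passing, which could be chance. Genes with a site as a group differed by −0.043 in C-26, against a median of −0.062 for permuted sites, which does not test a single gene.

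Mature miR-204-5p was not measured in these libraries, and Mir204 at 0 FPKM does not report it. A small RNA measurement of the same 9 RNAs would show which libraries carry it.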
